A study of Mus musculus with 16 samples.

How the data were processed

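Whole-lung homogenates from 16 mice were measured on Illumina MouseRef-8 v2 BeadChips, 1 array per mouse: 5 wild-type and 5 Mmp28 knockout mice after cigarette smoke, and 3 wild-type and 3 knockout mice in room air. Per the labels, smoke was given 3 hours a day on 5 days a week for 3 months from 7 to 9 weeks of age, and the concentration is given as 250 in a unit (tpm per cubic metre) that the labels do not define. Groups were taken from the labels, and 0 columns were left unassigned.

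The deposited signal table holds intensity values per probe and array on a linear scale, per the file headers, with no normalization between arrays and no background subtraction visible in the values. The detection p-value beside each intensity is, per the file headers, the deposited probability that the signal is background, and it moves in equal steps set by 798 negative controls. The authors also deposited a processed table of intensity values whose columns hold nearly the same set of values and keep the rank order of the signals. The authors name lumi for their processing, without a version or a step, and the kind of transformation is not stated.

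The signals were processed in R 4.3.3 with limma 3.58.1. Background was corrected by normexp with parameters inferred from the detection p-values and an offset of 16, followed by quantile normalization and log2. A probe was kept when its detection p was under 0.05 on at least 3 arrays, which kept 16126 of 25697 probes and left out 9571 as near background. Kept probes stood for 10879 genes, and 962 had no gene name and were counted but not named. For a gene with several kept probes, the probe with the highest mean over all arrays stood for it. Precision is limited by the number of arrays, since 3 arrays stand for each air group.

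A limma model of the 4 group means was fitted to all 16 arrays, with moderated variances (12 residual and 4.87 prior degrees of freedom). It gave 5 comparisons: smoke against air in wild type, smoke against air in knockout, knockout against wild type in air, knockout against wild type in smoke, and the interaction. The limma tests were two-sided and adjusted by Benjamini-Hochberg over all kept probes of a comparison, with a threshold of 0.05. The wild-type air arrays enter 3 of these comparisons.

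Lists of genes (27) were written from general knowledge: targets of the aryl hydrocarbon receptor (xenobiotic metabolism) and of NRF2, macrophage, chemokines and cytokines, neutrophil, T and NK cell, B and plasma cell, antigen presentation and dendritic cell, metalloproteinases and inhibitors without Mmp28, extracellular matrix and fibroblast, alveolar type 2 cell, alveolar type 1 cell, club and secretory airway epithelium, ciliated airway epithelium, endothelial, smooth muscle and pericyte, cell cycle, interferon response, cholesterol and fatty acid synthesis, lysosome and phagocytosis, clock, immediate early and heat shock, heart and skeletal muscle, adipose, erythroid and platelet, thymus and lymph node, and sex-linked genes. Each list with at least 5 measured genes was compared with all other genes by limma's camera with a preset correlation of 0.01, adjusted over the 130 tests of 26 lists and 5 comparisons. Camera with an estimated correlation and the rotation test fry were run beside it. The fry test asks whether a list's genes move on balance to 1 side, and its mixed form whether they move to either side.

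Genes named in the text followed a rule. Per comparison they were the 10 largest rises and 10 largest falls among genes that passed with every array of a group beyond the mean of the other group, or the 5 lowest p where under 5 genes passed. Per list they were up to 4 members with the lowest adjusted p, or the 2 lowest p where none passed and the list did. Up to 6 genes called in both smoke or both genotype comparisons, and called genes within 10 Mb of Mmp28, completed them. Genes named under the wild-type air replicate 1 pattern and Xist were chosen after their values were seen. A fold against a group with no detected array is given as a lower bound. Gene positions were used only to place genes within 5, 10 or 20 Mb of Mmp28, and the share of called genes there was tested by Fisher's exact test.

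The groups, comparisons, lists, naming rule and alternatives were fixed before the data were examined. Alternatives were no background correction, cyclic loess, the deposited processed values, no detection filter, a stricter filter (detection p under 0.01 on all arrays of a group), array weights, the replicate number as a block, only the 2 groups compared, other probes of a gene, and each array left out in turn. The BeadChip could not be used as a block, because the columns do not name it. The whole procedure was tested on simulated data with 200 changed genes. At a change of 2-fold it recovered 82.1% (wild-type smoke), 85.1% (knockout smoke), 67.2% (genotype in air), 88.1% (genotype in smoke) and 49.3% (interaction) of genes, and it called 3 to 15 unchanged probes. At 1.5-fold these shares were 43.3%, 28.4%, 10.4%, 47.8% and 7.46%, in the same order. The simulated noise was independent between genes, no array was made to stand apart, and changed genes were not drawn from the lowest levels. Recovery in the real data may therefore be lower.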

Results

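Total RNA from homogenised whole lungs was measured on Illumina MouseRef-8 v2 BeadChips, 1 array per mouse. The mice were C57BL/6 wild type or carried a deletion of Mmp28, a secreted matrix metalloproteinase, on the C57BL/6 background. They breathed room air or cigarette smoke for 3 months, and the 16 arrays comprised 5 wild-type smoke, 5 knockout smoke, 3 wild-type air and 3 knockout air lungs. The median signal per array lay between 132.5 and 166.3, and 13971 to 15238 of 25697 probes were detected (54.4% to 59.3%). The number of arrays limits the precision of every value below. Values after ± are standard errors of the limma fit on the log2 scale unless SD or SE is written, with n = 5 per smoke group and n = 3 per air group. The first principal component held 42.2% of the variance and separated the 10 smoke arrays from the 6 air arrays. The second held 17.1% and separated wild-type air replicate 1 (52.3) from the rest (-24.0 to 13.2).

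Mmp28 itself was read by 1 probe that passed the detection filter, and it was detected on every array of each group, the knockouts included. Its log2 level was 5.82 (SD 0.189, n = 3) in wild-type air, 5.69 (SD 0.316, n = 3) in knockout air, 5.99 (SD 0.329, n = 5) in wild-type smoke and 5.73 (SD 0.309, n = 5) in knockout smoke. The knockout minus wild-type difference in Mmp28 was -0.12 ± 0.22 in air (adjusted p = 0.847) and -0.26 ± 0.17 in smoke (adjusted p = 0.999). The other Mmp28 probe was detected on 0 arrays. The files do not say whether either probe lies in the deleted part of Mmp28, so these values do not test the genotype labels.

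Wild-type lungs after smoke were compared with wild-type lungs in air. The columns do not name the BeadChips, so any chip difference between the groups cannot be told apart from the exposure. Ear6, of the eosinophil-associated ribonuclease family, rose 22.0-fold (log2 4.46 ± 0.42), and Cxcr1, a chemokine receptor of neutrophils, rose 16.9-fold (log2 4.08 ± 0.32). The neutrophil list as a whole did not pass (median -0.21, 1 of 21 rose and 1 fell, camera adjusted p = 0.304). The acute phase gene Orm1, undetected in wild-type air, rose at least 7.25-fold, and Serpina3n, an acute phase protease inhibitor, rose 7.17-fold (log2 2.84 ± 0.19). Mmp12, the macrophage elastase, rose 5.79-fold (log2 2.53 ± 0.50), Gpnmb, a glycoprotein of lipid-laden macrophages, rose 5.53-fold (log2 2.47 ± 0.22), and Timp1, an inhibitor of metalloproteinases, rose 5.00-fold (log2 2.32 ± 0.30). Ch25h, which makes 25-hydroxycholesterol, rose by 2.77 ± 0.24, Spag11b by 2.58 ± 0.44 and Zranb3 by 2.44 ± 0.28 on the log2 scale. Zxda (-3.14 ± 0.34), Erich5 (-3.05 ± 0.40), Rhbdl2 (-2.88 ± 0.35), Itgad (-2.69 ± 0.30), Ccdc144b (-2.60 ± 0.27) and Gm7609 (-2.33 ± 0.26) fell, and Pisd-ps2 was undetected after smoke and at least 4.92-fold lower. Prf1, which encodes the pore-forming perforin of killer lymphocytes, fell by 2.57 ± 0.33, while its other probe gave -0.53 (adjusted p = 0.0822). Other Itgad probes gave -2.63 and -0.62. The red cell genes Slc4a1 (-2.97 ± 0.69) and Hbb-b2 (-2.56 ± 0.48) also fell; without wild-type air replicate 1, where Slc4a1 was high, its change was -1.83 (adjusted p = 0.0243).

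Extracellular matrix and fibroblast genes moved most as a group in wild-type lungs. Of 40 measured, 33 rose, 1 fell and 6 did not pass, with a median log2 change of 1.03. Col1a1 rose by 1.89 ± 0.14, Col5a1 by 1.73 ± 0.14, Sparc by 1.32 ± 0.12 and Bgn by 1.23 ± 0.12. Endothelial genes rose in 26 of 35, among them Car4 (1.74 ± 0.17), Emcn (1.19 ± 0.15) and Plvap (1.05 ± 0.16). Smooth muscle and pericyte genes rose in 12 of 15, with Des (1.51 ± 0.15), Acta2 (1.49 ± 0.17) and Tpm2 (1.35 ± 0.19). Alveolar type 1 cell genes rose in 12 of 21, including Emp2 (1.05 ± 0.17) and Pdpn (1.00 ± 0.16). Against the rest of the genes, these lists passed with adjusted p = 2.2e-19 (matrix), 1.57e-11 (endothelial), 3.41e-07 (smooth muscle) and 2.31e-06 (type 1). In the stricter form of the test the matrix list had adjusted p = 0.0941 with an estimated correlation. The endothelial list had adjusted p = 0.352 with an estimated correlation. The smooth muscle list had adjusted p = 0.0941 with an estimated correlation, and the type 1 list had adjusted p = 0.422 with an estimated correlation. Adjusted over the list alone, 34 matrix, 29 endothelial, 13 smooth muscle and 15 type 1 genes rose.

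Some macrophage genes and NRF2 targets rose as well. Of 37 macrophage genes 13 rose and 2 fell. Beside Gpnmb, the lysosomal tetraspanin Cd63 rose by 1.95 ± 0.19, the collagen-degrading protease Ctsk by 2.11 ± 0.26 and the scavenger receptor Marco by 1.59 ± 0.25 (list adjusted p = 0.0023, and adjusted p = 0.455 with an estimated correlation). Of 29 metalloproteinase and inhibitor genes 12 rose and 2 fell, with Mmp2 (1.69 ± 0.17), Mmp23 (1.36 ± 0.15) and Timp2 (1.12 ± 0.14) among the rises (list adjusted p = 0.00361, and adjusted p = 0.0941 with an estimated correlation). Of 23 targets of the oxidant sensor NRF2, 8 rose, among them Gstm1 (1.54 ± 0.15), Akr1b8 (1.38 ± 0.14) and Gstm2 (1.17 ± 0.11), and none fell (list adjusted p = 0.00664, and adjusted p = 0.343 with an estimated correlation). The other Gstm1 probe gave 0.24 (adjusted p = 0.54). Ciliated airway genes rose in 16 of 27 and fell in 1, with Rsph9 at 1.26 ± 0.30 and Sntn at 1.34 ± 0.34 (list adjusted p = 0.000274, and adjusted p = 0.647 with an estimated correlation). Wild-type air replicate 1 was low in these genes, and without it Rsph9 changed by 0.74 (adjusted p = 0.0251) and Sntn by 0.84 (adjusted p = 0.0492), and the list median fell from 0.85 to 0.39. The other Sntn probe gave 0.41 (adjusted p = 0.183). Chemokines and cytokines rose in 9 of 40 and fell in 1, with Ccl11 (1.64 ± 0.29), Il1a (1.54 ± 0.30) and Ccl6 (1.33 ± 0.19) among the rises (list adjusted p = 0.0378, and adjusted p = 0.626 with an estimated correlation). Lysosomal genes rose in 8 of 31 and fell in 1, such as Mcoln1 (0.89 ± 0.12) and Lamp1 (0.52 ± 0.10; list adjusted p = 0.0438, and adjusted p = 0.736 with an estimated correlation). The chemokine call was lost without wild-type smoke replicate 1 or wild-type air replicate 2 or 3 (highest adjusted p = 0.194), and the lysosome call without wild-type smoke replicate 1 or 3 or wild-type air replicate 2 or 3 (highest adjusted p = 0.352).

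Lymphocyte genes went the other way. T and NK cell genes fell in 20 of 33 and rose in 0, with Eomes, a transcription factor of cytotoxic cells, at -1.06 ± 0.18 and Klrd1 at -0.87 ± 0.16 beside Prf1 (list adjusted p = 2.58e-08, and adjusted p = 0.352 with an estimated correlation). B and plasma cell genes fell in 2 of 22, and in 0 adjusted over the list alone. They were Jchain (-0.63 ± 0.18) and Spib (-0.64 ± 0.20; list adjusted p = 0.0396, and adjusted p = 0.756 with an estimated correlation). Antigen presentation genes fell in 6 of 31, such as H2-DMb1 (-0.56 ± 0.12; list adjusted p = 0.0307, and adjusted p = 0.647 with an estimated correlation). Jchain no longer passed without wild-type air replicate 2 (adjusted p = 0.0573) or 3 (adjusted p = 0.124). Spib no longer passed without wild-type smoke replicate 4 (adjusted p = 0.0539) or 5 (adjusted p = 0.0578) or wild-type air replicate 3 (adjusted p = 0.149). The B cell list call was lost without wild-type smoke replicate 4 or 5 or wild-type air replicate 2 or 3 (highest adjusted p = 0.613), and the antigen presentation call without wild-type smoke replicate 5 or wild-type air replicate 1 or 3 (highest adjusted p = 0.136). Cell cycle genes fell in 8 of 38 and rose in 1, with Top2a at -1.07 ± 0.14 and Hmgb2 at -0.91 ± 0.14 (list adjusted p = 0.00664, and adjusted p = 0.647 with an estimated correlation). Interferon response genes fell in 14 of 40, among them Oas2 (-1.60 ± 0.29), Trim30a (-0.91 ± 0.16) and Irgm1 (-0.58 ± 0.10; list adjusted p = 3.84e-06, and adjusted p = 0.626 with an estimated correlation). Wild-type air replicate 1 was high in both sets, and without it the cell cycle list (adjusted p = 0.132) and the interferon list (adjusted p = 0.132) no longer passed, and Oas2 changed by -1.01.

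In all, 3158 genes passed in wild-type lungs, 1719 up and 1439 down, and 491 of them changed at least 2-fold. Per probe, limma called 4490 of 16126, 2322 up and 2168 down.

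**Figure D1:**
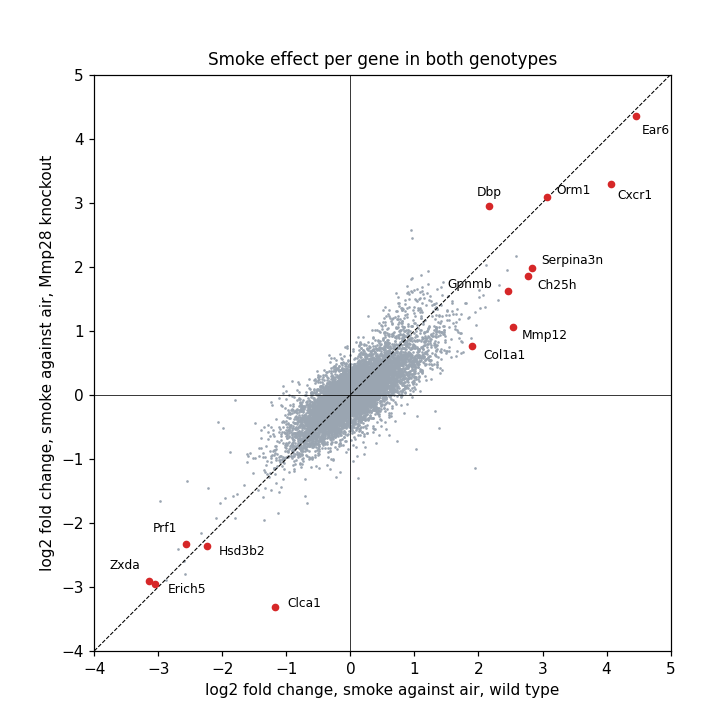
Each point is 1 of 10879 genes, placed by its log2 fold change with smoke in wild-type lungs (horizontal axis) and in Mmp28 knockout lungs (vertical axis); the dashed line marks equal change and red points are named genes. The cloud follows the diagonal with r = 0.796 across genes.

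Knockout lungs after smoke were compared with knockout lungs in air in the same way, with the same limit. Ear6 rose 20.4-fold (log2 4.35 ± 0.42), Cxcr1 9.83-fold (log2 3.30 ± 0.32), Orm1 8.53-fold (log2 3.09 ± 0.31) and Serpina3n 3.97-fold (log2 1.99 ± 0.19). The neutrophil list again did not pass (median -0.23, 1 of 21 rose and 1 fell, camera adjusted p = 0.222). Csf3r, the receptor for the neutrophil growth factor, changed by -1.145 (limma adjusted p = 0.0023), and its other probes gave -0.80 to -1.44. Dbp, a transcription factor of the circadian clock, rose by 2.95 ± 0.22, the xenobiotic cytochrome Cyp2a5 by 2.58 ± 0.51, Spag11b by 2.16 ± 0.44, the growth factor Igf1 by 2.02 ± 0.34, Zranb3 by 1.95 ± 0.28 and Nme5 by 1.93 ± 0.26. Zxda (-2.91 ± 0.34), Erich5 (-2.95 ± 0.40), Rhbdl2 (-2.89 ± 0.35), Ccdc144b (-2.60 ± 0.27), Itgad (-2.40 ± 0.30), Hsd3b2 (-2.36 ± 0.29), Prf1 (-2.33 ± 0.33) and Gm7609 (-2.16 ± 0.26) fell. Other probes gave -2.12 and -0.34 (adjusted p = 0.114) for Itgad and -0.75 for Prf1. Clca1, a product of mucous cells, and Pisd-ps2 were undetected in knockout smoke, and lay at least 7.71-fold and at least 5.78-fold below knockout air. Clca1 varied between the knockout air arrays (SD 2.91, n = 3), and its change no longer passed without knockout air replicate 1 (adjusted p = 0.0936) or 3 (adjusted p = 0.0799).

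Ciliated airway genes led the lists in knockout lungs. Of 27, 19 rose and 1 fell, with a median of 1.44, and Morn5 (1.59 ± 0.26), Mlf1 (1.57 ± 0.27) and Tekt1 (1.41 ± 0.26) are examples (list adjusted p = 1.56e-11, and adjusted p = 0.386 with an estimated correlation). Extracellular matrix genes rose in 19 of 40, including Tcf21 (1.16 ± 0.18), Mfap5 (1.20 ± 0.19), Inmt (1.08 ± 0.17) and Col5a1 (0.85 ± 0.14), with a median of 0.47 (list adjusted p = 5.37e-07, and adjusted p = 0.371 with an estimated correlation). Smooth muscle genes rose in 9 of 15, with Actg2 at 1.56 ± 0.18 and Acta2 at 1.25 ± 0.17 (list adjusted p = 3.35e-06, and adjusted p = 0.119 with an estimated correlation). Endothelial genes rose in 5 of 35, such as Car4 (0.82 ± 0.17) and Emcn (0.65 ± 0.15; list adjusted p = 0.000412, and adjusted p = 0.647 with an estimated correlation). NRF2 targets rose in 8 of 23 and fell in 1, with Akr1b8 (1.25 ± 0.14) and Gstm1 (1.17 ± 0.15) first (list adjusted p = 0.00163, and adjusted p = 0.228 with an estimated correlation). The other Gstm1 probe gave 0.25 (adjusted p = 0.546). Heart and skeletal muscle genes rose in 5 of 11 and fell in 1, among them Actc1 (1.42 ± 0.23) and Tcap (0.89 ± 0.14; list adjusted p = 0.0263, and adjusted p = 0.442 with an estimated correlation). That call was lost without knockout air replicate 2 (adjusted p = 0.0995).

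Cell cycle genes fell in 16 of 38 knockout measurements and rose in 0, with Top2a at -1.12 ± 0.14, Foxm1 at -0.73 ± 0.11 and Prc1 at -0.72 ± 0.14 (list adjusted p = 7.05e-07, and adjusted p = 0.382 with an estimated correlation). T and NK cell genes fell in 10 of 33, including Eomes (-0.75 ± 0.18) and Prf1 (list adjusted p = 7.01e-05, and adjusted p = 0.49 with an estimated correlation). Immediate early genes fell in 8 of 32, with Fos at -0.65 ± 0.11, Zfp36 at -0.49 ± 0.10 and Dusp1 at -0.60 ± 0.14 (list adjusted p = 0.00569, and adjusted p = 0.258 with an estimated correlation). Alveolar type 2 cell genes fell in 5 of 29 and rose in 1, with Acly at -0.39 ± 0.11 (list adjusted p = 0.00215, and adjusted p = 0.647 with an estimated correlation). Without knockout air replicate 3 the type 2 list (adjusted p = 0.0508) and Acly (-0.33, adjusted p = 0.0789) no longer passed. Adjusted over the list alone, 24 ciliated, 24 matrix, 10 smooth muscle, 5 endothelial and 12 NRF2 genes rose, and 18 cell cycle and 12 T and NK cell genes fell. In all, 2306 genes passed, 1219 up and 1087 down, 297 of them by at least 2-fold, and limma called 3236 probes (1651 up, 1585 down). Without knockout air replicate 1 the count was 2111 probes, over 1.5 times lower.

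The effects of smoke in the 2 genotypes, from separate arrays, had a Pearson r of 0.796 and a Spearman rho of 0.754 across 10879 genes, which are not independent replicates. Both comparisons called 884 genes up, with 193 by chance, and 752 genes down, with 144 by chance. Opposite calls came to 2 genes. Ear6, Cxcr1 and Orm1 led the shared rises, and Erich5, Zxda and Rhbdl2 the shared falls.

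**Figure D2:**
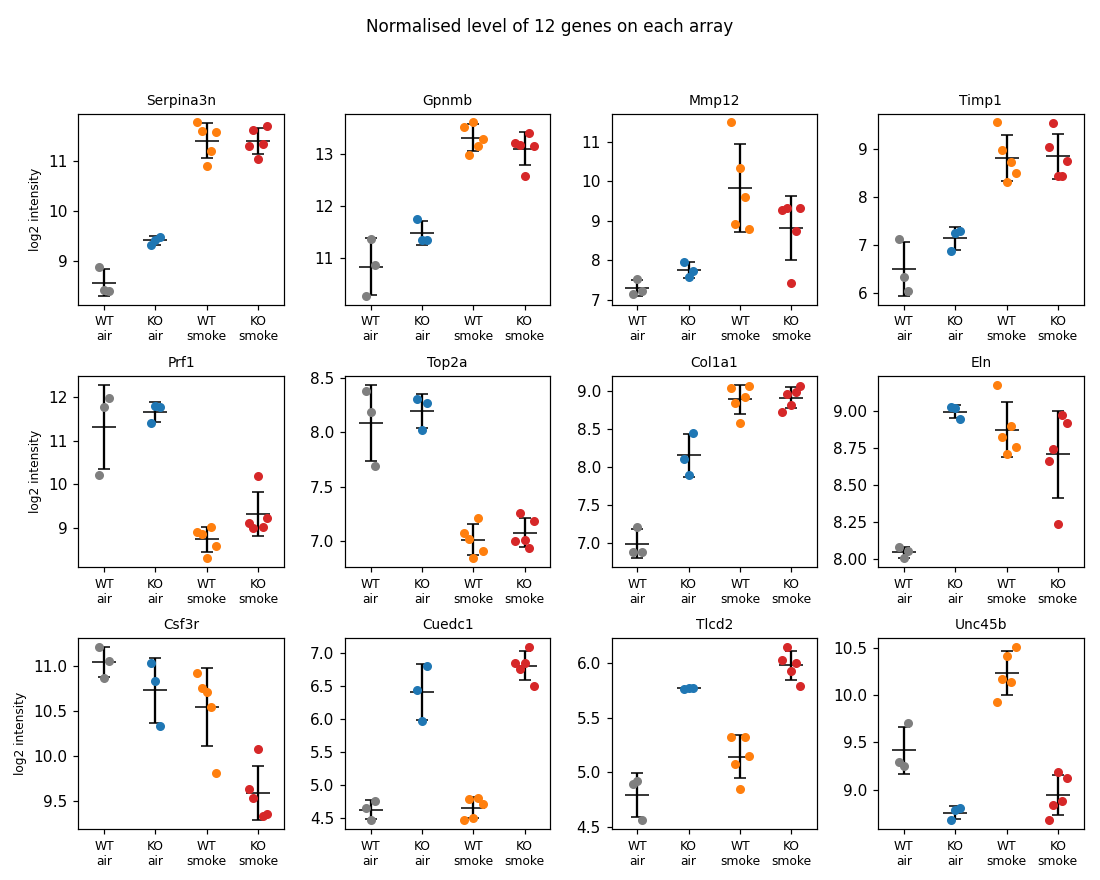
Normalised log2 intensity of 12 named genes on each of the 16 arrays, by group; points are arrays, and the bar and whiskers are the mean and 1 SD. Col1a1 averaged 7.00 in wild-type air, 8.15 in knockout air, 8.89 in wild-type smoke and 8.91 in knockout smoke.

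Knockout lungs were compared with wild-type lungs in air, without smoke. Whether a difference comes from the genotype stays open, because 3 arrays per group share any difference in how the pieces were taken. Rose and fell mean higher and lower in knockout here. Col1a1 rose by 1.16 ± 0.16, Col3a1 by 1.17 ± 0.22, Col1a2 by 1.10 ± 0.21 and Lum, a collagen-binding proteoglycan, by 1.28 ± 0.24. The other Col3a1 probe gave 0.11 (adjusted p = 0.797). Wt1, a transcription factor of the mesothelium, rose by 1.35 ± 0.26, the lipid kinase Sphk1 by 1.35 ± 0.26, Gpm6a by 1.29 ± 0.23, the chloride channel Ano1 by 1.23 ± 0.24 and Gdf10 by 1.13 ± 0.22. Cuedc1, undetected on all wild-type arrays, was at least 2.78-fold higher. The falls were Cnpy3 (-0.87 ± 0.17), Sys1 (-0.85 ± 0.17), Mylpf (-0.83 ± 0.13) and Nek4 (-0.62 ± 0.12). In all 37 genes passed, 33 up and 4 down, from 44 probes. That count of probes was 1 without knockout air replicate 1 or 3, 2 without wild-type air replicate 1, 3 without wild-type smoke replicate 2 or 4 or knockout smoke replicate 1 or 2, and 6 without knockout smoke replicate 4. It was 22 without wild-type smoke replicate 3, 81 without wild-type air replicate 3 and 117 without wild-type air replicate 2. It was 0 on the deposited processed values and 0 with only the 2 groups in the fit, against 132 with the replicate block. Of the 20 named genes called here 19 lost their call without some array, Col1a1 among them without wild-type air replicate 1 (adjusted p = 0.0615), and Cuedc1 kept it throughout.

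The matrix genes were higher in knockout air lungs as a group. Of 40, 12 rose over all genes tested and 32 adjusted over the list alone, with a median of 0.62, and Eln (0.95 ± 0.16), Fbln1 (0.85 ± 0.15) and Sparc (0.81 ± 0.14) were among them (list adjusted p = 2.11e-25, and adjusted p = 0.0941 with an estimated correlation). Without wild-type air replicate 1 the adjusted p was 0.145 for Eln, 0.148 for Fbln1 and 0.145 for Sparc, and without knockout air replicate 3 it was 0.241 for each. Other probes gave 0.74 for Sparc (adjusted p = 0.0909), and 0.86 (adjusted p = 0.0543) and 0.52 (adjusted p = 0.319) for Fbln1. The list's level on the wild-type air arrays was -1.01 to -0.63, below all knockout air arrays (-0.28 to 0.05). Of 21 type 1 genes, 1 rose, Emp2 (0.92 ± 0.19; adjusted p = 0.173 without wild-type air replicate 1), and 18 adjusted over the list alone (median 0.85; adjusted p = 1.79e-15, and adjusted p = 0.148 with an estimated correlation). Of 35 endothelial genes 0 passed over all genes and 20 rose adjusted over the list alone, such as Sox18 at 0.82 ± 0.18 (list adjusted p = 1.35e-14, and adjusted p = 0.28 with an estimated correlation). The type 2 list was higher with Il33 at 1.04 ± 0.34 (list adjusted p = 3.84e-06, and adjusted p = 0.49 with an estimated correlation). Its median of 0.57 fell to 0.20 without wild-type air replicate 1 (adjusted p = 0.00503). The metalloproteinase list was higher with Timp2 at 0.74 ± 0.16 (list adjusted p = 0.00514, and adjusted p = 0.0985 with an estimated correlation). The smooth muscle list was higher with Myocd at 0.54 ± 0.15 (list adjusted p = 0.00664, and adjusted p = 0.394 with an estimated correlation), and so was the cholesterol and fatty acid synthesis list with Fads1 at 0.55 ± 0.15 (list adjusted p = 0.00308, and adjusted p = 0.442 with an estimated correlation). The metalloproteinase call was lost without wild-type air replicate 3 (adjusted p = 0.12). Sox18, Il33, Timp2, Myocd and Fads1 did not pass themselves (lowest adjusted p = 0.0549), and the other Myocd probe gave -0.19.

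Lower in knockout air was the interferon list with Oasl1 at -0.96 ± 0.30 (list adjusted p = 1.17e-08, and adjusted p = 0.496 with an estimated correlation). The neutrophil list was lower with Ltf at -1.10 ± 0.39 (list adjusted p = 0.000461, and adjusted p = 0.422 with an estimated correlation), and the blood list with Gp1bb at -0.76 ± 0.36 (list adjusted p = 0.0131, and adjusted p = 0.647 with an estimated correlation). Wild-type air replicate 1 was high in these lists, and without it the interferon list had adjusted p = 0.543, the neutrophil list 0.133 and the blood list 0.686. The cholesterol list, on which this array was low, had adjusted p = 0.0775 without it. The blood call was also lost without wild-type air replicate 2 or knockout air replicate 1. Ciliated genes were lower, with Morn5 at -0.61 ± 0.29 and a list median of -0.30 (list adjusted p = 0.00325, and adjusted p = 0.736 with an estimated correlation). Oasl1, Ltf, Gp1bb and Morn5 did not pass themselves (lowest adjusted p = 0.168), and the other Morn5 probe gave -0.10. The ciliated median was -0.73 without wild-type air replicate 1, -0.10 without wild-type air replicate 2, -0.16 without wild-type air replicate 3, -0.19 without knockout air replicate 2 and -0.49 without knockout air replicate 3. The call was lost without wild-type air replicate 2 or 3 or knockout air replicate 2 (highest adjusted p = 0.377).

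**Figure D3:**
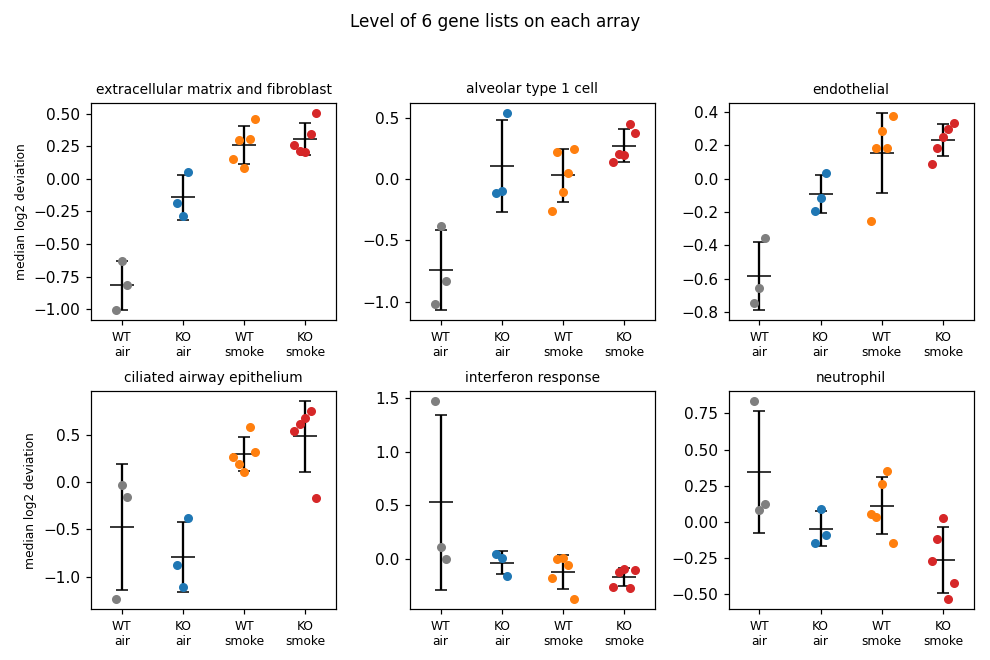
Level of 6 gene lists on each array, as the median over the list's genes of the log2 deviation from the mean of all 16 arrays; the bar and whiskers are the mean and 1 SD of each group. The matrix list lies between -1.01 and -0.63 in wild-type air and between -0.28 and 0.51 elsewhere, and wild-type air replicate 1 stands at 1.47 in the interferon list.

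Knockout lungs were also compared with wild-type lungs after smoke, and rose and fell again mean higher and lower in knockout. Cuedc1 was at least 3.74-fold higher in knockouts, Tlcd2 rose by 0.83 ± 0.11 (adjusted p = 0.00281), and Unc45b, a chaperone of muscle myosin, fell by 1.29 ± 0.13 (adjusted p = 9.71e-05). These were the 3 genes that passed on the probe that stood for them. Per probe, limma called 7 (4 up, 3 down), among them another probe of Csf3r (-0.81, adjusted p = 0.0448). The count of probes was 11 under a stricter detection filter, 11 with the replicate block and 21 with array weights. Next by p were Nle1 (0.77 ± 0.14, adjusted p = 0.0525) and Mid1 (-0.77 ± 0.14, adjusted p = 0.0542). Nle1 lies 0.54 Mb from Mmp28 and was 0.83 higher in knockout than in wild-type air (adjusted p = 0.0543). Cuedc1 and Tlcd2 also rose in air, Tlcd2 by 0.98 ± 0.14 (adjusted p = 0.0701 without knockout air replicate 1 and 0.0934 without replicate 3). The other Tlcd2 probe gave 0.68 in air and did not pass (adjusted p = 0.0517). Cuedc1 and Tlcd2 were the only genes called in both genotype comparisons, whose effects had a Pearson r of 0.261 across genes. Without wild-type air replicate 1 that r was 0.0862, over 1.5 times lower.

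The neutrophil list was lower in knockout than in wild-type lungs after smoke by camera with the preset correlation. Of 21 genes, 0 passed over all genes and 6 fell adjusted over the list alone, with a median of -0.44 (list adjusted p = 4.14e-10, and adjusted p = 0.119 with an estimated correlation). Fry gave adjusted p = 0.108. List levels overlapped, at -0.144 to 0.349 in wild-type smoke and -0.534 to 0.0291 in knockout smoke. The list was also lower in knockout air (median -0.395). Its interaction did not pass (median 0.0145, camera adjusted p = 0.951), but did without wild-type air replicate 1 (median -0.23, adjusted p = 0.0316). The receptor for the neutrophil growth factor, Csf3r, was -0.96 ± 0.20 (adjusted p = 0.151) and the chemokine receptor Cxcr2 was -0.86 ± 0.21 (adjusted p = 0.498). The other probes of Csf3r gave -0.26 to -0.81, the last with adjusted p = 0.0448. The chemokine list was lower with Il1b at -0.73 ± 0.22 and Cxcl1 at -0.59 ± 0.18 (list adjusted p = 9.92e-06, and adjusted p = 0.258 with an estimated correlation). The immediate early list was lower with Atf3 at -0.54 ± 0.15 (list adjusted p = 7.01e-05, and adjusted p = 0.0941 with an estimated correlation). The lysosome list was lower with Man2b1 at -0.20 ± 0.10 (list adjusted p = 0.000529, and adjusted p = 0.567 with an estimated correlation), as was the macrophage list with Il1rn at -0.59 ± 0.16 (list adjusted p = 0.00168, and adjusted p = 0.442 with an estimated correlation). The other Il1rn probe gave 0.03 (adjusted p = 0.999). The cell cycle list was lower with Cdk1 at -0.35 ± 0.14 (list adjusted p = 0.00425, and adjusted p = 0.647 with an estimated correlation). The macrophage (adjusted p = 0.173) and lysosome (adjusted p = 0.0579) calls were lost without knockout smoke replicate 3, and the cell cycle call without wild-type smoke replicate 1 or knockout smoke replicate 4 (highest adjusted p = 0.247). None of the genes named with these lists passed on the probe used here (lowest adjusted p = 0.151).

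Higher in knockout smoke was the T and NK cell list with Nkg7 at 0.59 ± 0.13 (list adjusted p = 3.6e-07, and adjusted p = 0.381 with an estimated correlation). The type 1 list was higher with Clic3 at 0.43 ± 0.18 (list adjusted p = 2.97e-05, and adjusted p = 0.49 with an estimated correlation), as was the clock list with Dbp at 0.83 ± 0.19 and Tef at 0.70 ± 0.17 (list adjusted p = 0.000248, and adjusted p = 0.352 with an estimated correlation). Adjusted over the list alone 4 of 15 clock genes rose. The ciliated list was higher with Spag16 at 0.36 ± 0.14 (list adjusted p = 0.00135, and adjusted p = 0.707 with an estimated correlation), as was the club cell list with Cyp2b10 at 0.48 ± 0.22 (list adjusted p = 0.00299, and adjusted p = 0.647 with an estimated correlation). The B cell list was higher with Vpreb3 at 0.47 ± 0.16 (list adjusted p = 0.00506, and adjusted p = 0.707 with an estimated correlation), as was the heart muscle list with Tcap at 0.36 ± 0.12 (list adjusted p = 0.0492, and adjusted p = 0.496 with an estimated correlation). These calls were lost without knockout smoke replicate 4 (ciliated, adjusted p = 0.0786), wild-type smoke replicate 2 (club, 0.0581), and wild-type smoke replicate 5 (B cell, 0.455). The heart muscle call was lost without wild-type smoke replicate 1, 2 or 4, knockout smoke replicate 1, 2 or 3, or wild-type air replicate 1, 2 or 3 (highest adjusted p = 0.327). None of the genes named with these lists passed itself (lowest adjusted p = 0.214), and the other Cyp2b10 probe gave 0.23.

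The genes called in smoke, each judged by the 1 probe that stood for it, lie near Mmp28 on chromosome 11. Within 10 Mb of Mmp28, 3 of 176 genes passed in smoke and 0 of 10697 elsewhere (Fisher's exact test, two-sided, p = 4.17e-06), namely Cuedc1, Tlcd2 and Unc45b. On the absolute changes of all genes in the window, limma's camera, a model-based and not an exact test, gave p = 0.0417 in smoke and p = 0.811 in air, and in smoke p = 0.252 within 5 Mb and p = 0.286 within 20 Mb. In air 3 of 176 passed, Cuedc1, Tlcd2 and Slc6a4 (0.94 ± 0.19), against 34 elsewhere (Fisher's exact p = 0.0217), and without wild-type air replicate 2 that p was 0.062. It was 0.288 in a window of 5 Mb, 0.0755 in a window of 20 Mb, 0.164 with no background correction and 1 on the deposited processed values. Slc6a4 no longer passed without wild-type smoke replicate 2, 3 or 4, knockout smoke replicate 1, 2 or 4, wild-type air replicate 1, or any of the knockout air arrays (highest adjusted p = 0.241). Tlcd2 and Unc45b had another probe each that gave 0.82 and -1.37 in smoke.

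The last question, whether smoke changed knockout lungs differently from wild-type lungs, was tested as the interaction. The lowest p values belonged to Col1a1 (-1.14 ± 0.20), the elastic fibre gene Eln (-1.12 ± 0.21), Phf8 (0.94 ± 0.18), Med22 (-0.75 ± 0.16) and Retnla, a marker of alternatively activated macrophages (-1.87 ± 0.40). None passed, with adjusted p between 0.392 and 0.509, and the other Med22 probe gave -0.15. limma called 0 probes, and 1194 had an unadjusted p under 0.05. As a group, matrix genes changed less with smoke in knockout than in wild-type lungs, with a median difference of -0.55 and 19 of 40 lower adjusted over the list alone (list adjusted p = 8.59e-23, and adjusted p = 0.0941 with an estimated correlation). The same 3 wild-type air arrays enter the interaction, the wild-type smoke comparison and the genotype comparison in air. Between the genotypes after smoke the matrix list differed by a median of 0.07 and did not pass (adjusted p = 0.191).

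Further lists differed in their response to smoke between the genotypes. Lower and higher here refer to the change with smoke, knockout minus wild type, and not to the level. The level of the type 1 list was higher in knockouts in air (median 0.852) and after smoke (0.272). That of the interferon list was lower in both (-0.451 and -0.0509). For chemokine genes the level after smoke went with the interaction (-0.172), while in air it was 0.0751. Lower in knockouts was the endothelial list with Car4 at -0.92 ± 0.24 (list adjusted p = 6.92e-11, and adjusted p = 0.352 with an estimated correlation). The type 1 list was lower with Emp2 at -0.80 ± 0.23 (list adjusted p = 6.52e-09, and adjusted p = 0.352 with an estimated correlation), as was the chemokine list with Il6 at -1.23 ± 0.34 (list adjusted p = 0.000118, and adjusted p = 0.352 with an estimated correlation). The metalloproteinase list was lower with Timp2 at -0.73 ± 0.20 (list adjusted p = 0.000301, and adjusted p = 0.0941 with an estimated correlation). So was the cholesterol list with Fads1 at -0.62 ± 0.20 (list adjusted p = 0.000312, and adjusted p = 0.352 with an estimated correlation). The immediate early list was lower with Fos at -0.43 ± 0.16 (list adjusted p = 0.000504, and adjusted p = 0.119 with an estimated correlation), as was the macrophage list with Gpnmb at -0.85 ± 0.31 (list adjusted p = 0.00185, and adjusted p = 0.442 with an estimated correlation). The type 2 list was lower with Abca3 at -0.58 ± 0.30 (list adjusted p = 0.000817, and adjusted p = 0.647 with an estimated correlation), as was the cell cycle list with Bub1b at -0.77 ± 0.23 (list adjusted p = 0.00868, and adjusted p = 0.647 with an estimated correlation). Higher in knockouts was the ciliated list with Fank1 at 0.78 ± 0.37 (list adjusted p = 3.84e-06, and adjusted p = 0.607 with an estimated correlation), as was the T and NK cell list with Cd4 at 0.49 ± 0.21 (list adjusted p = 0.00114, and adjusted p = 0.607 with an estimated correlation). The B cell list was higher with Vpreb3 at 0.78 ± 0.26 (list adjusted p = 0.0139, and adjusted p = 0.736 with an estimated correlation), as was the interferon list with Zbp1 at 0.92 ± 0.36 (list adjusted p = 9.9e-07, and adjusted p = 0.607 with an estimated correlation). Without wild-type air replicate 1 the interferon median was -0.02 (adjusted p = 0.933), without wild-type air replicate 3 the T and NK cell list had adjusted p = 0.121, and without wild-type air replicate 1 or knockout air replicate 3 the type 2 list was lost (highest adjusted p = 0.29). The cell cycle call was lost without knockout smoke replicate 4, wild-type air replicate 3 or knockout air replicate 2 (highest adjusted p = 0.545), and the B cell call without wild-type smoke replicate 5, wild-type air replicate 2 or 3, or knockout air replicate 3 (highest adjusted p = 0.882). None of the genes named with these lists passed itself (lowest adjusted p = 0.529), and other Gpnmb probes gave -1.09, -0.37 and -0.29.

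Over all 5 comparisons 63 of 130 list tests passed with the preset correlation, and 0 of these held with an estimated correlation. The rotation test fry, which asks only whether a list's genes moved on balance 1 way and compares them with no other genes, called 23 of the 63 in its form for a single direction. With smoke in wild type it called, for example, the matrix (adjusted p = 9.43e-06), smooth muscle (1.16e-05) and NRF2 lists (0.000195). It did not call the ciliated (0.117), interferon (0.108) or B cell list (0.397) there. Between the genotypes after smoke it called only the immediate early list (0.0308). Lists for xenobiotic metabolism, adipose tissue and thymus or lymph node passed in 0 comparisons, and the list of sex-linked genes had 2 measured members and was not tested. Single xenobiotic genes did pass with smoke: of 9, 4 rose and 0 fell in wild type, and 1 rose and 0 fell in knockout.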

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

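The tests of the array wild-type air replicate 1, of the matrix genes in wild-type air, of other Cuedc1 probes and of genes near Mmp28 ranked by p were chosen only after the results were seen. The bound for more immune cells in wild-type air was changed after its own result, from an SE over genes (ciliated list -0.734 ± 0.074, SE over genes, which argued against it) to an SE over arrays, which leaves it open.

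Splits of the same arrays into other groups of the same sizes bear on the counts. Chance is argued against for smoke in wild type. The real split called 4490 probes and the highest other 3, and 1 of 56 splits, the real one, reached the real count. The same holds for smoke in knockout (3236 against 5, again 1 of 56). Chance is not excluded, because 56 splits allow no smaller share than 1 of 56. Splits that mix smoke and air arrays also put the smoke difference into the spread, which lowers their counts. For the genotype in smoke 2 of 100 drawn splits, the real one included, reached the real count. The real split called 7 probes, and the highest other, which exchanged 1 knockout array, called 9. This argues against chance but does not exclude it, since a split that mixed the genotypes called more. For the genotype in air 10 splits are too few; the real split called 44 probes and the highest other 9, and 1 reached the real count. The interaction called 0 probes, so that 100 of 100 regroupings reached it was fixed beforehand. The highest called 62, which may point to a structure of the samples that was not tested.

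The genes called for genotype in smoke, each judged by the 1 probe that stood for it, lay near Mmp28. Chance is argued against, but not excluded, by the 3 genes lowest in p of each split, a number set by the genes called in the real split. All 3 lay near Mmp28 in the real split and at most 1 in any other (1 of 100 drawn splits, the real one, reached 3). The Fisher p of 4.17e-06, against a lowest other of 1, decides nothing because 97 of the 99 other splits called 0 genes. A sequence variant under single probes of Tlcd2 and Unc45b is argued against, because another probe of each changed by at least 0.991 times as much. For Cuedc1 there were 0 other kept probes, so a variant under its probe stays open. Flanking DNA of another strain may be the source and also stays open: the genotype effects in air and smoke across 172 genes near Mmp28, called genes left out, had r = 0.317, under the 95th percentile of other windows (0.437), but that bound was wrong as a test because leaving out called genes cannot exclude variants that reach a few genes, and an effect of Mmp28 itself is open too.

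Wild-type air replicate 1 stood apart, with Saa3 at 12.2 on the log2 scale against 5.24 to 6.59 on the other air arrays, Prtn3 at 9.01 and Vsig4 at 9.39. Poor hybridisation is argued against, although 13971 probes were detected against 14439 to 15238, because the interferon list was higher by a median of 1.46 ± 0.15 (SE over genes, 38 of 40 higher). Lymphoid tissue in the piece of lung is argued against by the B and plasma cell list, at -0.921 ± 0.15 (SE over genes, 21 of 22 lower). Genes of a list move together, and a single array is compared, so these SEs do not measure the spread between arrays. An animal with inflammation or infection may be the source, and this was not tested. The ciliated list was also lower on it, by a median of -1.14.

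Matrix genes were low in wild-type air lungs. A single outlying array is argued against, since without wild-type air replicate 1 the list had adjusted p = 5.32e-26 (highest over leave-outs of an air array 1.9e-17; with all arrays, adjusted p = 0.0941 with an estimated correlation), and its level was -1.01 to -0.63 on the wild-type and -0.28 to 0.05 on the knockout air arrays. More immune cells in the wild-type air lungs stay open: without that array type 1 (0.7), endothelial (0.414), type 2 (0.201), B and plasma cell (-0.459) and T and NK cell (-0.161) genes, knockout minus wild type, went with them, and ciliated (-0.734), macrophage (0.0963) and chemokine (0.27) genes against them, but with all air arrays the levels (SE over arrays) were -0.313 ± 0.44 for ciliated, -0.0989 ± 0.39 for B and plasma cell and -0.0326 ± 0.14 for T and NK cell genes. More airway in the wild-type air pieces may contribute and cannot be told apart from the genotype, because the club list, at -0.0923 ± 0.16 (SE over genes), lay within its error of 0. An effect of the genotype stays open, and 3 arrays per group share any difference in how the pieces were taken.

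Single arrays lay far from the rest of their smoke group in 26 of 334 group tests, where chance gives about 1 in 20 groups (16.7 here), and knockout smoke replicates 3 and 5 held 8 and 9. The values below are the gap to the nearest array over the range of the group. Knockout smoke replicate 3 was lowest in the macrophage list (0.911), Zranb3 (0.749), Pdpn (0.72) and Cnpy3 (0.85), and highest in Erich5 (0.783), Rhbdl2 (0.809), Prf1 (0.811) and Gm7609 (0.76). Knockout smoke replicate 5 was lowest in the ciliated list (0.767), Rsph9 (0.728), Sntn (0.736), Nme5 (0.799), Morn5 (0.824), Mlf1 (0.718), Med22 (0.725) and Vpreb3 (0.818), and highest in the thymus and lymph node list (0.758). Knockout smoke replicate 4 was lowest in the B and plasma cell list (0.862) and Cd4 (0.779). Wild-type smoke replicate 1 was lowest in Mcoln1 (0.795), replicate 2 highest in Cnpy3 (0.778), and replicate 3 highest in Prtn3 (0.714) and Vsig4 (0.816). Wild-type smoke replicate 5 was lowest in Il1b (0.711) and Oasl1 (0.799) and highest in Nr1d1 (0.77).

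The response to smoke differed between the genotypes in 14 lists by the interaction with the preset correlation, and in 0 with an estimated correlation. The median log2 difference, knockout minus wild type, was -0.554 for matrix, -0.597 for alveolar type 1, -0.449 for endothelial, -0.407 for alveolar type 2, -0.337 for chemokine, -0.258 for immediate early, -0.236 for metalloproteinase, -0.232 for macrophage, -0.193 for cholesterol and -0.155 for cell cycle genes. It was 0.458 for ciliated, 0.453 for interferon, 0.24 for T and NK cell and 0.216 for B and plasma cell genes. Without wild-type air replicate 1 the value was 0.926 for ciliated, -0.019 for interferon, 0.389 for T and NK cell, 0.558 for B and plasma cell, -0.0965 for type 2 and -0.263 for cell cycle genes. Without wild-type air replicate 2 it was 0.274 for ciliated, 0.732 for interferon, -0.695 for type 2 and -0.209 for chemokine genes. Without wild-type air replicate 3 it was 0.751 for interferon, 0.0883 for T and NK cell, -0.0788 for B and plasma cell and -0.0598 for cell cycle genes. The B and plasma cell value was 0.379 without knockout air replicate 2, 0.0511 without knockout air replicate 3, 0.11 without wild-type smoke replicate 5 and 0.345 without knockout smoke replicate 4. Metalloproteinase genes gave -0.151 without knockout air replicate 3, and without knockout smoke replicate 3 macrophage genes gave -0.15 and T and NK cell genes 0.157.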

How the results depend on the processing

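All alternatives were planned, and none was added after the results were seen. The cause was not tested for any change below except where stated. The counts for smoke stayed within 1.5 times the main count under every alternative to the processing in both genotypes. The interaction called 0 probes under each alternative run for it, which leaves out the fit of only the 2 groups. The block by BeadChip was not run, because the columns do not name the chips.

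For the genotype in air, 44 probes became 13 with no background correction, 0 on the authors' processed values, 16 with no filter, 69 with the strict filter, 7 with array weights, 132 with the replicate block and 0 with only the 2 groups compared, which leaves fewer arrays to estimate the spread. For the genotype in smoke, 7 became 11 with the strict filter, 21 with array weights and 11 with the replicate block. The replicate numbers do not pair the animals (r between same-numbered arrays -0.21 to 0.16). Agreement of smoke effects was 0.821 on the authors' processed values, and agreement of genotype effects was 0.119 with array weights. The Fisher test near Mmp28 in air gave 0.164 with no background correction, 1 on the authors' processed values, 0.288 at 5 Mb and 0.0755 at 20 Mb. Of 63 list calls, 0 held with an estimated correlation, and fry made 25 calls, 23 of them among the 63.

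Leaving out each array in turn gave 3692 to 4721 probes for smoke in wild type, 2111 to 4036 for smoke in knockout, 1 to 117 for genotype in air, 5 to 10 for genotype in smoke and 55 to 67 list calls. Agreement of smoke effects ran from 0.734 to 0.815, agreement of genotype effects from 0.0862 to 0.34, and the Fisher p in air from 0.000261 to 0.062. The interferon list turned in the interaction without wild-type air replicate 1 (-0.01903, adjusted p = 0.933; up to 0.751 without other arrays). The club list turned without knockout air replicate 2 (-0.3261, adjusted p = 0.0242; up to 0.358 without other arrays).

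Of 235 gene calls named by the rule, 214 held with no background correction, 227 with cyclic loess, 207 on the authors' processed values, 215 with no filter, 219 with array weights, 219 with the replicate block and 209 with only the 2 groups, and 0 turned direction. With another probe of the gene 61 of 87 held, and with the strict filter 226 of 226. The log2 changes were smaller on the authors' processed values (median ratio 0.662) and with no background correction (0.797).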

Other observations

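The values here were looked at only after the results were seen, and no explanation was tested. Xist, which is expressed from the inactive X chromosome, was detected on all 16 arrays. Its mean log2 level was 9.96 in wild-type air, 10.17 in knockout air, 8.15 in wild-type smoke and 8.25 in knockout smoke, a change with smoke of -1.81 and -1.92. Another Xist probe changed by -1.40 and -1.31. Uty, on the Y chromosome, lay near background, at 4.80 to 5.30 in the group means. It was detected on 2 of 3 wild-type air, 3 of 3 knockout air, 3 of 5 wild-type smoke and 3 of 5 knockout smoke arrays.

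Other probes of the same gene backed falls less often than rises. Among probes called down by at least 2-fold with smoke in wild type, 36 of 87 with other probes had these change, by their median, under 0.5 times the called value, against 27 of 181 called up (Fisher's exact test, two-sided, p = 5.11e-06). In knockout these were 25 of 57 and 23 of 121 (Fisher's exact p = 0.000962). Each called probe was counted, so probes of the same gene are not independent and these p values do not measure a spread between genes.

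Of 15 clock genes 3 rose and 3 fell with smoke in wild type (list adjusted p = 0.433, limma), and 6 rose and 3 fell in knockout (list adjusted p = 0.114, limma), and the rest did not pass. Dbp rose by 2.17 in wild type and 2.95 in knockout, Tef by 0.71 and 1.31, and Nr1d1 by 1.33 and 1.05, while Arntl changed by -0.62 and -0.98. Tef no longer passed in wild type without wild-type air replicate 1 (limma, adjusted p = 0.0603), nor did Arntl without wild-type air replicate 2 (limma, adjusted p = 0.0591).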
